A study of Mus musculus with 2 samples.

How the data were processed

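Single-cell RNA sequencing was done on mononuclear cells of mouse plantaris muscle. Per the labels, 1 plantaris muscle of each of 5 male C57BL/6 mice, 12 weeks old, was subjected to tenotomy, and the muscle of the other side was the sham control. After 4 days the 5 muscles of a group were pooled and digested with collagenase, and living cells were sorted as Calcein AM positive and propidium iodide negative. Each pool gave 1 library made with the 10x Chromium Next GEM 3-prime chemistry. The tendon that was cut is not given in the sources used here.

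The deposited files hold raw counts, that is, unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization. The processing notes of the authors name Cell Ranger 4.0.0 and mm10. The values were whole numbers, and the lowest total of a barcode was 500 UMIs in both libraries. The sham file held 8463 barcodes with 47781353 UMIs in total, and the tenotomy file held 11950 barcodes with 94556283 UMIs. Of 32285 gene identifiers in the files, 32235 were found in the GENCODE mouse annotation on the mm10 assembly, which supplied the coordinates. The annotation used by the authors is not stated.

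Cells were kept with at least 300 genes, at least 500 UMIs and at most 10% mitochondrial UMIs. The gene limit was missed by 136 sham and 190 tenotomy barcodes, and the mitochondrial limit by 715 and 697. Doublet scores came from the scrublet method in scanpy 1.11.5, run on each library. Its automatic threshold called 1 sham cell and 320 tenotomy cells, so the threshold of the tenotomy library, 0.212, was used for both. It removed 190 of 7738 sham cells (2.46%) and 320 of 11237 tenotomy cells (2.85%), which left 7548 and 10917 cells. Kept cells had a median of 4851 UMIs and 1847 genes in sham and of 5859 UMIs and 1993 genes in tenotomy.

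Both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log transformed, 2000 variable genes were chosen per library and combined, and 30 principal components and 15 neighbours went into Leiden clustering at resolution 1. The 39 clusters were named from fixed marker lists, so the class names were rebuilt here and are not the authors'. A class needed a score of at least 0.58, at least 3 markers in at least 10% of the cells of the cluster, a median of at least 25% of cells per marker, and a second class at no more than 0.57 of the best. A cluster also stayed unnamed where markers of another class outnumbered its own among its 10 leading genes, or where its cells were shallow and no own marker led. These limits were set after the cluster scores had been seen. They left 10 clusters unnamed, with 6.24% of the sham and 1.49% of the tenotomy cells, and gave 14 named classes. Of these, 9 held at least 50 cells in each library and were compared gene by gene.

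Within a class, UMIs were summed per library and scaled by the total of the class to give CPM. A gene was measured if the library with the higher value had at least 50 CPM and at least 25 UMIs, and if that value was at least 10% of the CPM over all kept cells of the same library. This free RNA limit is meant to leave out genes that free RNA could bring, but genes of other cells can pass it. The neutrophil gene S100a9 did so in pericyte or smooth muscle-like cells of the tenotomy library, at 26.4%. Folds are tenotomy over sham with an exact conditional binomial 95% interval. A gene with 0 counts on one side was taken at 3 counts, and its fold is written as a lower bound. Shares of cells have exact Clopper-Pearson 95% intervals, and ratios of shares have 95% intervals on the log scale. With 1 library per group there is no replicate, so no test across samples was possible, and treatment and library are confounded. All intervals and floors cover counting error only.

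The named genes follow a rule of size fixed before the data were examined. Genes at least 2-fold apart were ranked by the interval bound nearest to 1, and up to 12 each way are named in mesenchymal progenitor-like, muscle stem cell-like and monocyte/macrophage-like cells, with up to 6 each way in other classes. Mitochondrial genes, ribosomal protein genes and uncharacterised gene models were left out, as were myofibre, erythroid and antigen receptor segment genes outside their own class. The rule also names 14 genes whatever their values, and the members of each described list with the largest folds. Markers of the classes and 24 gene lists were fixed at the same time. A list member counts as measured with at least 25 UMIs in the class over both libraries. The median log2 fold of a list of at least 5 measured members was placed among 10000 random lists of the same size matched on expression in 20 bins, as a description of these libraries. The list symbols Cyr61, Ctgf, Wisp1 and Mx1 were absent from the files; the first 3 are older names of genes listed under their present symbols.

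A cell counted as carrying cycle transcripts with at least 2 UMIs over 12 genes (Mki67, Top2a, Cdk1, Ccnb1, Ccnb2, Cenpf, Birc5, Ube2c, Hmmr, Nusap1, Ccna2 and Tpx2) after each cell had been thinned to 1000 UMIs. Thinning left out 254 sham and 476 tenotomy cells with fewer UMIs.

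Alternatives fixed before the data were examined changed the cell filter, the mitochondrial limit, doublet removal, the clustering resolution, joint clustering, the genes used for clustering, the scaling, the weighting of cells, the depth, free RNA, the expression limits, the cycle limits and the cells counted in a share. Further alternatives, chosen after the data had been seen, used the automatic doublet calls, allowed a second class of up to 0.6 of the best, and left out cells with at least 2 UMIs of the 12 cycle genes before thinning. The steps for folds, intervals and list percentiles were tested on simulated class totals. These were Poisson counts from the mean profile of each of 4 classes at the depths of the libraries, with 200 genes of known change. The cell filter, doublet removal, clustering, naming, thinning and free RNA limit were not part of this test. The draws held no spread between cells or libraries, so the test shows only how the steps act under counting error. All of the genes changed 3-fold or 6-fold passed the 2-fold limit in the 4 classes, 0% of the unchanged genes did, and the intervals covered the true value for 94.8% to 95.6% of the 2883 to 3173 genes. Lists without a change fell outside the central 95% of random lists in 2% to 5% of 100 lists per class.

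Tools were python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9. Comparisons of dendritic cell-like, T or natural killer cell-like, Schwann-like, erythroid-like and lymphatic endothelial-like cells gene by gene were left out because a library held fewer than 50 of them.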

Results

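The data are UMI counts per gene and cell from 1 sham and 1 tenotomy library of mouse plantaris muscle, taken 4 days after tenotomy, each a pool of the muscles of 5 mice. The comparison addressed here is which living mononuclear cells, and which transcripts within them, differed between the 2 sides. The sham library held 47781353 UMIs in 8463 barcodes and the tenotomy library 94556283 UMIs in 11950 barcodes. After filtering, 7548 sham and 10917 tenotomy cells were kept, with medians of 4851 and 5859 UMIs per cell. No replicate exists for any value below, so every difference is between 1 library and 1 other, and the intervals in brackets are 95% intervals for counting error. Class names end in "-like" because they were rebuilt from fixed marker genes.

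Monocyte/macrophage-like cells made up 5.31% (4.82 to 5.84) of the living cells sorted as Calcein AM positive and propidium iodide negative in the sham library and 42.0% (41.1 to 43.0) in the tenotomy library, a ratio of 7.91 (7.18 to 8.73). The other immune classes were larger in the tenotomy library as well. Dendritic cell-like cells made up 0.291% and 5.77%, neutrophil-like cells 0.927% and 6.27%, B cell-like cells 0.702% and 2.16%, and T or natural killer cell-like cells 0.344% and 1.21%. Blood endothelial cell-like cells, the largest class of the sham library, made up 43.3% (42.2 to 44.4) there and 13.8% (13.2 to 14.5) in the tenotomy library, a ratio of 0.319 (0.302 to 0.337). Mesenchymal progenitor-like cells, the class that holds fibro-adipogenic progenitors, made up 24.7% (23.8 to 25.7) and 16.4% (15.7 to 17.1), and muscle stem cell-like cells 6.62% (6.07 to 7.21) and 4.81% (4.42 to 5.23). Tenocyte-like cells made up 5.26% and 1.89%, pericyte or smooth muscle-like cells 3.92% and 1.75%, Schwann or other glial cell-like cells 0.967% and 0.385%, and lymphatic endothelial-like cells 0.318% and 0.192%. Myofibre-like cells made up 0.715% and 0.660%. The ratios of the last 2 classes, 0.605 (0.337 to 1.09) and 0.922 (0.649 to 1.31), were within counting error.

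**Figure D1:**
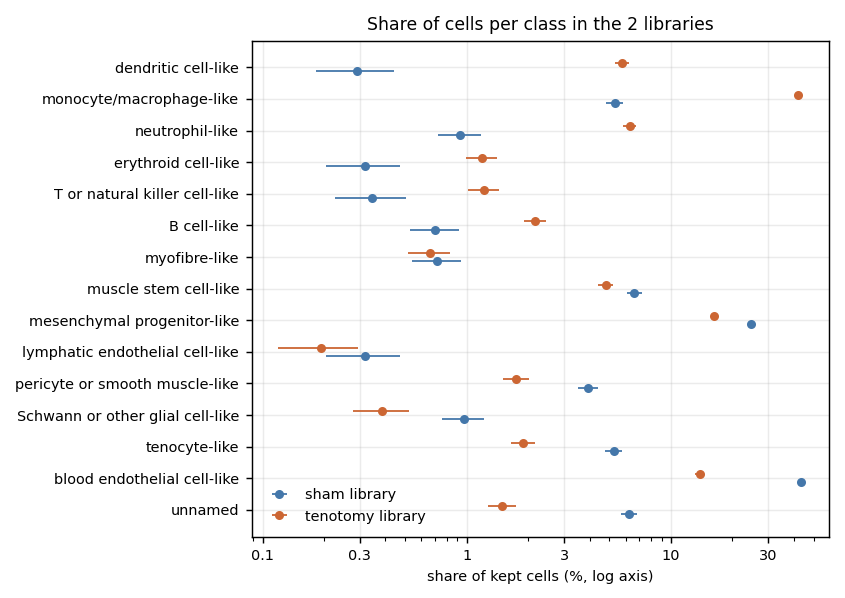
Share of kept cells per class in percent on a log axis for the sham and the tenotomy library (1 library each), with exact 95% intervals for counting error as bars. Immune classes had higher shares in the tenotomy library, with monocyte/macrophage-like cells the largest at 42.0% against 5.31%. Blood endothelial cell-like, tenocyte-like and pericyte-like cells had lower shares.

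Shares of a whole move together, so the ratios were also taken without the classes that differed most. Among cells other than blood endothelial cell-like cells, the share of monocyte/macrophage-like cells was 9.37% in sham and 48.8% in tenotomy, a ratio of 5.21, and the ratios of mesenchymal progenitor-like and muscle stem cell-like cells were 0.435 and 0.478. Among cells other than monocyte/macrophage-like cells, the share of mesenchymal progenitor-like cells was 26.1% and 28.2%, and that of muscle stem cell-like cells was 7.0% and 8.30%. Blood endothelial cell-like cells had a share of 45.8% and 23.9% on that base. Clusters without a name held 6.24% of sham and 1.49% of tenotomy cells. Those that scored best as mesenchymal progenitors held 365 sham cells (4.84%) and 69 tenotomy cells (0.632%), and with them the ratio of that class was 0.574 in place of 0.661. Of these sham cells, 260 were in a cluster with a median of only 1184.5 UMIs per cell. Over the alternative settings the ratio ranged from 0.389 to 0.706 for mesenchymal progenitor-like cells and from 0.301 to 0.775 for muscle stem cell-like cells.

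Cells with transcripts of bone marrow precursors were more frequent in the tenotomy library. Granulocyte precursor genes (at least 3 UMIs per cell thinned to 1000 UMIs, over genes such as Elane, Mpo and Ngp) marked 1.02% of sham and 3.70% of tenotomy cells. Erythroid precursor genes such as Car1 and Klf1 marked 0.0685% and 1.12%, and B cell precursor genes such as Vpreb1 and Rag1 marked 0.233% and 0.987%. Erythroid-like cells made up 0.318% of sham and 1.19% of tenotomy cells, and 8.33% (2 of 24) and 69.0% (89 of 129) of them carried cycle transcripts. In the neutrophil-like class, 44.3% (31 of 70, 32.4 to 56.7) of sham and 60.0% (352 of 587, 55.9 to 64.0) of tenotomy cells carried granulocyte precursor genes, with overlapping intervals. Unnamed clusters held a further 33 sham and 17 tenotomy cells with these genes, so the sham share depends on the naming of clusters. These marker lists were chosen after the erythroid and neutrophil clusters had been seen.

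Mesenchymal progenitor-like cells of the tenotomy library carried more transcripts of extracellular matrix, TGF-beta response and cell cycle genes than those of the sham library, and fewer transcripts of Smoc2/Cxcl14 progenitor genes. Of 3562 genes measured in 1867 sham and 1785 tenotomy cells, 579 were at least 2-fold higher and 587 at least 2-fold lower in the tenotomy library, and 494 and 661 with the fold divided by the median fold of all measured genes. Tnc, which encodes the matrix glycoprotein tenascin C (mm10, chromosome 4, 63959785 to 64047015), was at 1.17 CPM in sham and 1570 CPM in tenotomy, 1336-fold higher (856 to 2220). Postn, the gene of periostin (chromosome 3, 54361109 to 54391037), was 406-fold higher (354 to 467), from 12.9 to 5217 CPM. Cthrc1, a secreted collagen-related protein (chromosome 15, 39076932 to 39087121), was 310-fold higher (226 to 438). Acta2 and Tagln, smooth muscle contractile genes that myofibroblasts also express, were 189-fold (147 to 249) and 98.4-fold (81.1 to 121) higher.

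The remaining genes with the largest differences in this class covered other functions. Il1rl1, the receptor of interleukin 33, was 1119-fold higher (383 to 5428), and Timp1, an inhibitor of matrix proteases, 128-fold higher (115 to 143). Spp1, which encodes osteopontin, was 149-fold higher (108 to 212) and stood at 19.6% of its level in monocyte/macrophage-like cells of the same library, where C1qa, a macrophage gene, stood at 2.07% in the same class. Chl1 was 298-fold, Lrrc15 167-fold, Pclaf 112-fold and Nt5dc2 86.1-fold higher. Among genes lower in the tenotomy library, Gsn (gelsolin, chromosome 2, 35256380 to 35307892) was at 34510 CPM in sham and 2040 CPM in tenotomy, 16.9-fold lower (16.8 to 17.1). Inmt was 49.2-fold lower (42.4 to 57.3), Ces1d 56.4-fold lower (41.2 to 79.4) and Myoc 20.9-fold lower (20.2 to 21.5). G0s2, Angptl7, Lvrn, Zbtb16, Col4a4, Enpp2 and Sorl1 were 16.3-fold to 29.3-fold lower. Pdgfra, the receptor gene that marks this class (chromosome 5, 75152292 to 75198215), was 4.23-fold lower (4.07 to 4.40).

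Gene lists fixed in advance differed in this class as groups. In the extracellular matrix list, 22 of 43 measured genes were at least 2-fold higher, 10 at least 2-fold lower and 11 within 2-fold, with a median log2 fold of 1.05, above 100% of random lists. Beside Tnc, Postn and Timp1, Thbs4 was 28.5-fold higher (26.7 to 30.5), while the proteoglycan gene Dcn was 6.95-fold lower (6.91 to 6.998). In the TGF-beta response list, 13 of 23 genes were at least 2-fold higher and 4 lower, with a median of 1.22 above 100% of random lists. Of 36 cell cycle genes, 33 were at least 2-fold higher and 0 lower, with a median of 3.74, and Top2a, a topoisomerase of dividing cells, was 42.0-fold higher (29.8 to 61.1). Glycolysis and hypoxia genes had a median of 1.12, with 12 of 22 at least 2-fold higher and 1 lower, and the lactate transporter gene Slc16a3 was 16.0-fold higher (12.1 to 21.5). Nuclear oxidative phosphorylation genes had a median of 0.66, with 7 of 29 at least 2-fold higher and 0 lower. Of these, Cox5a was 3.60-fold higher (3.41 to 3.81). Mitochondrially encoded transcripts had a median of −0.39 at the 11.4th percentile, with 0 of 13 at least 2-fold higher and 3 lower. Ribosome biogenesis genes had a median of 0.67, with 8 of 25 at least 2-fold higher and 3 lower, among them Npm1 at 2.25-fold higher (2.20 to 2.31) and Myc at 3.83-fold lower (3.66 to 4.01).

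Chemokine and cytokine genes were mostly higher in mesenchymal progenitor-like cells of the tenotomy library, and Smoc2/Cxcl14 progenitor genes were mostly lower. Of 29 genes in the chemokine and cytokine list, 18 were at least 2-fold higher and 2 lower, with a median log2 fold of 1.40 above 100% of random lists, and 7 stood below the free RNA limit. Cxcl5, a neutrophil chemokine, was 66.7-fold higher (56.8 to 79.1), and Ccl11, an eosinophil chemokine, was 12.4-fold lower (11.9 to 12.9). In the Smoc2/Cxcl14 progenitor list, 13 of 18 genes were at least 2-fold lower and 3 higher, with a median of −2.13 below all random lists. Vwa1 was 11.1-fold lower (10.0 to 12.3) and Hsd11b1 9.88-fold lower (9.31 to 10.5), while Adam12 was 33.3-fold higher (25.7 to 44.1). The unnamed cluster of 260 sham and 2 tenotomy cells that carried Smoc2 and Cxcl14 stood outside this class. It was left unnamed for markers of 2 classes, with blood endothelial cells second. Its median was 1184.5 UMIs and 0.349% mitochondrial UMIs per cell, against 8173 and 3.11% in cluster 8 of this class, so its cells may be of poor quality. In the Pi16/Dpp4 list, 6 of 14 genes were at least 2-fold lower and 2 higher, with a median of −0.77 that was 0.26 after thinning, 0.05 as a mean over cells and 0.29 with the libraries clustered apart. Quiescence genes had a median of −1.30, with 11 of 18 at least 2-fold lower and 0 higher, and Cdkn1c, a cell cycle inhibitor, was 8.70-fold lower (8.14 to 9.30). Adipogenic genes had a median of −1.46 with 5 of 7 at least 2-fold lower and 4 of the 7 below the free RNA limit, and Lpl was 5.97-fold lower (5.78 to 6.18).

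YAP/TAZ target genes had a median log2 fold of 0.16 and a mean of −0.08, at the 74.3rd percentile, with 6 of 27 at least 2-fold higher and 5 lower. Their measured extremes were Ccdc80 at 3.52-fold higher (3.43 to 3.62) and F3, the gene of tissue factor, at 7.01-fold lower (6.51 to 7.55). Growth factor and load-response genes had a median of −0.23 and a mean of 0.44, with 7 of 25 at least 2-fold higher and 6 lower. Ccn4, a secreted WNT-induced protein, was 76.8-fold higher (54.6 to 112), Angptl4 23.7-fold higher (20.3 to 27.7), and Bmp4, a growth factor, 7.75-fold lower (7.05 to 8.54). Immediate early and stress genes had a median of −1.88, with 18 of 26 at least 2-fold lower and 1 higher. Markers of other cells were also higher, with a median of 1.66 for resident macrophage genes, 13 of 20 of which stood below the free RNA limit, and of 3.61 for MHC class II genes, where all 6 did. Inflammatory monocyte genes had a median of 2.38, and 8 of 17 stood below that limit. Of the class, 69.1% of tenotomy cells were in cluster 10, which held 0.107% of the sham cells, and 60.8% of sham cells were in cluster 8, which held 6.05% of the tenotomy cells, so a state of one library and the library itself are not separated. Without the cells carrying at least 2 cycle UMIs before thinning, a setting chosen after the data were seen that left 1849 sham and 1105 tenotomy cells, 369 genes were at least 2-fold higher.

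Muscle stem cell-like cells of the tenotomy library carried transcripts of dividing myoblasts and of early muscle fibres that were nearly absent from those of the sham library. Of 3468 genes measured in 500 sham and 525 tenotomy cells, 994 were at least 2-fold higher and 600 at least 2-fold lower in the tenotomy library. With the fold divided by the median fold of all measured genes, 0.24 on the log2 scale, these counts were 803 and 762. Myog, the transcription factor of myogenic differentiation (chromosome 1, 134289989 to 134292548), was at 4.26 CPM in sham and 691 CPM in tenotomy, 162-fold higher (96.7 to 297). Its 14 UMIs in sham came from 0.6% of the cells, and the interval does not cover the spread between cells. Mymk and Mymx, which encode the fusion proteins myomaker and myomixer, had 0 UMIs in sham and were at least 180-fold and at least 125-fold higher. The sarcomere genes Tnnt2, Actc1, Myh3 and Tnni1 also had 0 UMIs in sham and were at least 585-fold, 541-fold, 186-fold and 148-fold higher, and Cav3, the gene of caveolin 3, was at least 88.8-fold higher. Ttn, the gene of titin, was 565-fold higher (260 to 1541). Pax7, the transcription factor of muscle stem cells (chromosome 4, 139737062 to 139833528), was 2.13-fold lower (1.85 to 2.45), and Myod1 was 1.28-fold lower (1.18 to 1.39). These folds compare shares of the UMIs of the class, whose cells had medians of 5964.5 UMIs in sham and 13529 in tenotomy. A Pax7 UMI was seen in 40.2% of sham and 44.2% of tenotomy cells, and a Myod1 UMI in 26.0% and 52.4%.

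Genes outside the muscle programme differed in muscle stem cell-like cells as well. Spp1 had 1 UMI in sham and 4880 in tenotomy, a ratio of 1853 (332 to 73198), and stood at 32.4% of its level in monocyte/macrophage-like cells, where C1qa stood at 2.32% in muscle stem cell-like cells. Lgals3, the gene of galectin 3, was 191-fold higher (96.9 to 443), and Prune2, with 2 UMIs in sham, had a ratio of 244 (67.3 to 2015). Markers of other cells were higher too, with a median log2 fold of 3.13 for inflammatory monocyte genes and 2.13 for resident macrophage genes, where 8 of 16 and 12 of 16 stood below the free RNA limit. S100a8, a neutrophil gene, stood at 0.50% of its level over all cells in sham and 19.3% in tenotomy. Among lower genes, Nppc, which encodes C-type natriuretic peptide, was 39.7-fold lower (33.8 to 47.0). Erfe was 18.1-fold lower (16.3 to 20.1), and Chrdl2, a BMP antagonist used here as a stem cell marker, was 18.5-fold lower (15.8 to 21.9). The chemokine genes Ccl19 and Cxcl1 were 20.6-fold (15.8 to 27.3) and 14.0-fold (13.2 to 14.9) lower. The imprinted non-coding RNAs Meg3 and Mirg, which lie in 1 region of chromosome 12, were 13.3-fold (12.7 to 13.9) and 17.1-fold (11.8 to 25.7) lower. Gem, Zbtb16, Btg2, Maff and Slc10a6 were 13.03-fold to 17.5-fold lower.

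The fixed lists gave the same picture by group in muscle stem cell-like cells. Of 32 myogenic commitment and differentiation genes, 27 were at least 2-fold higher and 1 lower, with a median log2 fold of 4.22 above 100% of random lists, and the 1 lower was Myf5 at 3.39-fold (3.11 to 3.70). Of 36 cell cycle genes, 35 were at least 2-fold higher and 0 lower, with a median of 4.54, and Ccna2 (2 UMIs in sham) and Hmmr (2 UMIs) had ratios of 128 (35.3 to 1059) and 103 (28.5 to 856). Quiescence genes had a median of −1.74 below all random lists, with 14 of 19 at least 2-fold lower. Calcr, the calcitonin receptor gene of quiescent stem cells, was 13.6-fold lower (9.68 to 19.6), while Cdkn1c was the 1 member at least 2-fold higher, by 22.7-fold (19.8 to 26.1). Nuclear oxidative phosphorylation genes had a median of 1.54, with 20 of 29 at least 2-fold higher and 0 lower, led by Sdhd at 6.54-fold (5.26 to 8.24) and Uqcrc1 at 5.79-fold (4.79 to 7.06). Mitochondrially encoded transcripts had a median of −0.13, with 0 of 13 at least 2-fold higher and 1 lower. Glycolysis genes had a median of 1.01 at the 98.2nd percentile, with 11 of 22 at least 2-fold higher, led by Eno1 at 10.0-fold (8.49 to 11.9). YAP/TAZ target genes had a median of 0.26 at the 27.5th percentile, with 5 of 24 at least 2-fold higher and 5 lower. Immediate early and stress genes had a median of −2.32, with 24 of 26 at least 2-fold lower and 0 higher. Cluster 24 held 79.8% of the tenotomy and 0.60% of the sham cells of the class, and cluster 23 held 20.2% and 99.4%.

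**Figure D2:**
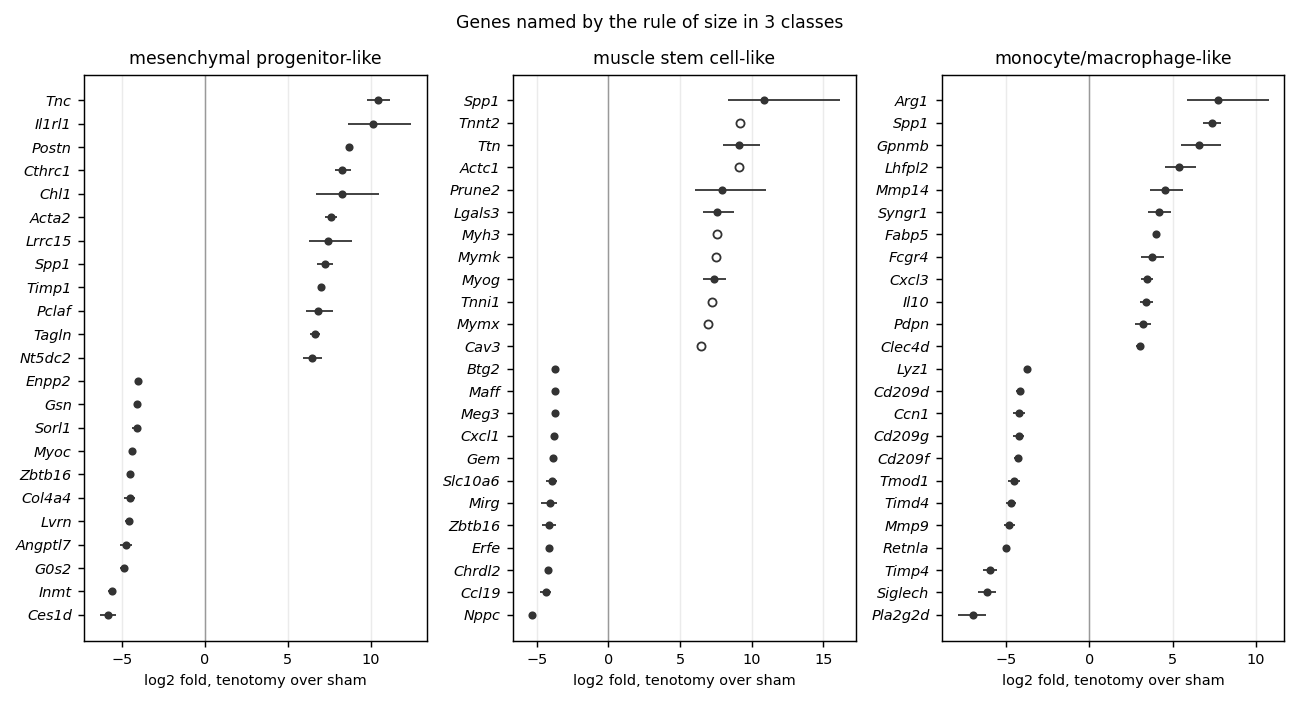
Log2 fold of tenotomy over sham for genes that the rule of size named in 3 classes, with 95% intervals for counting error as lines and open circles for genes with 0 UMIs in sham, taken at 3 counts and so lower bounds. Among the highest were matrix genes and Il1rl1 in mesenchymal progenitor-like cells, Spp1 with sarcomere and fusion genes in muscle stem cell-like cells, and Spp1, Arg1 and Gpnmb in monocyte/macrophage-like cells.

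Monocyte/macrophage-like cells of the tenotomy library carried more transcripts of lipid handling and phagocytosis genes and fewer of resident macrophage and MHC class II genes. Of 3232 genes measured in 401 sham and 4590 tenotomy cells, 205 were at least 2-fold higher and 248 at least 2-fold lower, and with the fold divided by the median fold of all measured genes (0.10 on the log2 scale) the counts were 163 and 294. Spp1 (chromosome 5, 104435118 to 104441050) was at 10.7 CPM in sham and 1739 CPM in tenotomy, 163-fold higher (115 to 240). Gpnmb, a glycoprotein of phagocytic macrophages, was 94.9-fold higher (46.1 to 236), and Fabp5, a fatty acid binding protein, was 15.8-fold higher (13.9 to 18.1). Arg1, the gene of arginase 1, had 2 UMIs in sham and 4319 in tenotomy, a ratio of 211 (58.3 to 1741). Lhfpl2 was 41.3-fold, Mmp14 23.4-fold, Syngr1 17.9-fold, Fcgr4 13.5-fold, Cxcl3 10.8-fold, Il10 10.7-fold, Pdpn 9.26-fold and Clec4d 8.17-fold higher.

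Genes lower in the tenotomy library included several that mark resident macrophages. Retnla was at 3377 CPM in sham and 106 CPM in tenotomy, 31.9-fold lower (30.6 to 33.2), and Timd4, a receptor of apoptotic cells, was 25.7-fold lower (20.8 to 31.8). The lectin genes Cd209f, Cd209g and Cd209d were 19.3-fold (16.8 to 22.4), 18.7-fold (15.1 to 23.2) and 17.5-fold (14.8 to 20.7) lower. Pla2g2d was 126-fold lower (73.0 to 235), Siglech 68.9-fold lower (47.3 to 103), Mmp9 27.5-fold lower (21.7 to 35.0), Tmod1 22.6-fold lower (17.3 to 29.7) and Lyz1 13.3-fold lower (12.6 to 14.1). Timp4 and Ccn1 were 60.3-fold and 18.2-fold lower, and in the sham class they stood at 17.3% and 25.5% of their level over all sham cells. Ccr2, the receptor of Ccl2, was 1.96-fold higher (1.80 to 2.15) and Igf1 2.35-fold lower (2.16 to 2.56).

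In the lipid and phagocytosis list, 11 of 21 genes were at least 2-fold higher and 2 lower, with a median log2 fold of 1.0 above 100% of random lists. Arg1, Spp1, Gpnmb and Fabp5 led it and Fabp4 was 6.67-fold lower (6.40 to 6.96). Fabp4 is also among the blood endothelial markers and capillary metabolism genes used here, and the source of its transcripts was not tested. In the resident macrophage list, 10 of 23 genes were at least 2-fold lower, 1 higher and 12 within 2-fold, with a median of −0.89 below all random lists. The complement gene C1qa was 1.16-fold lower (1.14 to 1.18) and C1qb 0.01 apart on the log2 scale, while Ccl8 was 5.73-fold higher (4.94 to 6.69). C1qa and C1qb are named here after their values were seen. MHC class II genes had a median of −0.94 at the 0.08th percentile, with 4 of 10 at least 2-fold lower and 0 higher, and H2-Eb1 was 2.03-fold lower (1.99 to 2.08). Growth factor and load-response genes had a median of 0.70 with 7 of 16 at least 2-fold higher and 2 lower, led by Vegfa at 6.49-fold (4.91 to 8.76) and Thbs1, and 6 of the 16 stood below the free RNA limit. Glycolysis and hypoxia genes had a median of 0.54 with 7 of 22 at least 2-fold higher, led by Hilpda at 7.80-fold (6.32 to 9.74). Type I interferon genes had a median of 0.51, with 8 of 23 at least 2-fold higher and 4 lower, from Irf7 at 5.14-fold higher (4.05 to 6.62) to Cxcl10 at 4.48-fold lower (4.17 to 4.80).

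Inflammatory monocyte genes had a median log2 fold of 0.25 at the 88.0th percentile in monocyte/macrophage-like cells, with 3 of 17 at least 2-fold higher and 1 lower, and Ptgs2, the gene of cyclooxygenase 2, was 5.55-fold higher (4.75 to 6.53). Chemokine and cytokine genes had a median of 0.33 with 9 of 29 at least 2-fold higher and 8 lower, and this median was −0.08 at the lower clustering resolution. Immediate early and stress genes had a median of −1.38, with 19 of 26 at least 2-fold lower and 0 higher. YAP/TAZ target genes had a median of −0.84 with 10 of 23 at least 2-fold lower and 4 higher, and 6 of the 23 stood below the free RNA limit. Capillary metabolism genes, which are markers of endothelial cells, had a median of −3.38. Cluster 16 held 72.6% of the sham and 2.05% of the tenotomy cells of the class, cluster 17 held 11.2% and 27.7%, cluster 20 held 10.7% and 32.9%, and cluster 18 held 0 of 401 sham cells and 21.2% of the tenotomy cells.

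Blood endothelial cell-like cells of the tenotomy library carried more transcripts of endothelial activation and cell cycle genes, and fewer of capillary metabolism genes. Of 3416 genes measured in 3270 sham and 1509 tenotomy cells, 201 were at least 2-fold higher and 227 at least 2-fold lower. Apln, a peptide of sprouting endothelial cells (chromosome X, 48025146 to 48034853), was 32.0-fold higher (23.0 to 45.6), and Col18a1, the gene of a basement membrane collagen, 28.9-fold higher (21.3 to 40.2). Pclaf, a replication factor, was 79.8-fold higher (40.0 to 187), AA467197 30.6-fold, Fam167b 18.7-fold and Wfdc17 16.3-fold higher. Timp4, an inhibitor of matrix proteases (chromosome 6, 115241892 to 115252205), was at 2232 CPM in sham and 328 CPM in tenotomy, 6.81-fold lower (6.51 to 7.14). Cyp26b1, an enzyme that breaks down retinoic acid, was 7.61-fold lower (6.07 to 9.67), and Spaar, Hrct1, Btnl9 and Btg2 were 7.25-fold, 6.64-fold, 5.61-fold and 5.19-fold lower.

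In the endothelial activation list, 8 of 16 genes were at least 2-fold higher and 1 lower, with a median log2 fold of 1.11 above 100% of random lists. Lrg1 was 14.1-fold higher (12.4 to 16.0) and the cytokine genes Csf3 and Il6 10.8-fold (9.05 to 12.9) and 10.1-fold (9.17 to 11.1) higher. Capillary metabolism genes had a median of −1.01 below all random lists, with 8 of 14 at least 2-fold lower and 0 higher, led by Timp4, Btnl9 and Car4, a carbonic anhydrase, at 3.89-fold lower (3.52 to 4.32). Angiogenesis and tip cell genes had a median of 0.30 at the 97.2nd percentile, within the central 95% of random lists, with 8 of 18 at least 2-fold higher and 2 lower, from Apln and Pgf, at 8.54-fold higher (6.95 to 10.6), to Kdr, a VEGF receptor, at 2.05-fold lower (1.97 to 2.13). Of 36 cell cycle genes, 27 were at least 2-fold higher and 0 lower, with a median of 2.69, and Top2a was 11.4-fold higher (8.74 to 15.2). Matrix and TGF-beta response genes had medians of 0.92 and 1.59, with Mmp14 13.9-fold higher (10.2 to 19.2) and Acta2 8.29-fold higher (6.66 to 10.4); 25 of 42 and 7 of 22 of their members stood below the free RNA limit. Lists of immune cells were higher too, with medians of 1.94 for inflammatory monocyte, 1.43 for resident macrophage, 2.76 for MHC class II and 2.02 for chemokine and cytokine genes, and 9 of 14, 14 of 19, 6 of 6 and 15 of 23 members stood below that limit. Immediate early and stress genes had a median of −1.15, with 16 of 26 at least 2-fold lower and 0 higher. Cluster 2 held 63.9% of the tenotomy and 2.63% of the sham cells of the class, and cluster 0 held 8.61% and 51.3%. Cluster 15, with Selp, Sele, Csf3 and Lrg1 among its leading genes, held 6.43% of the tenotomy and 1.44% of the sham cells.

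**Figure D3:**
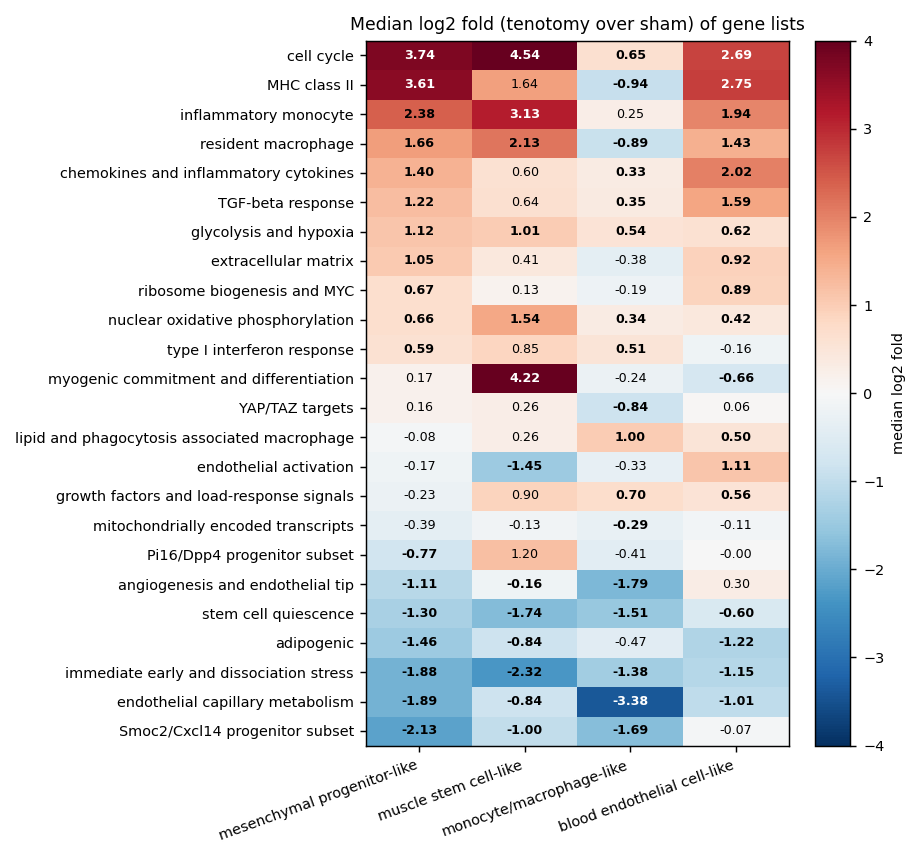
Median log2 fold of tenotomy over sham for 24 fixed gene lists (vertical) in 4 classes (horizontal), as colour and number, with bold type for medians outside the central 95% of random lists matched on expression. Immediate early and stress genes had a negative median and cell cycle genes a positive median in all 4 classes. Some lists of other cell types had many members below the free RNA limit, and the source of their transcripts was not tested.

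Thbs1, Cd47 and further genes were fixed for reporting in advance whatever their values. Thbs1, the gene of the secreted protein thrombospondin 1 (chromosome 2, 118111876 to 118127133), was 6.25-fold higher (5.87 to 6.67) in monocyte/macrophage-like, 10.2-fold higher (7.70 to 13.7) in muscle stem cell-like and 3.62-fold higher (3.20 to 4.11) in blood endothelial cell-like cells of the tenotomy library, and 1.16-fold higher (1.13 to 1.18) in mesenchymal progenitor-like cells. Its level in tenotomy was 14.0% of that over all cells in muscle stem cell-like and 10.3% in blood endothelial cell-like cells. Of all Thbs1 UMIs, monocyte/macrophage-like cells held 4.63% in sham and 61.3% in tenotomy, and mesenchymal progenitor-like cells 58.6% and 27.0%. Cd47, a receptor of thrombospondin 1, was 1.79-fold higher (1.59 to 2.01) in muscle stem cell-like cells. It was 1.81-fold lower (1.76 to 1.87) in mesenchymal progenitor-like cells and 1.52-fold lower (1.43 to 1.61) in blood endothelial cell-like cells. Folds compare shares of the UMIs of a class, and mesenchymal progenitor-like cells had medians of 8506 UMIs in sham and 14892 in tenotomy. In that class Cd47 had 8375 UMIs in 1867 sham and 8924 in 1785 tenotomy cells. Grn, the gene of progranulin, was 1.72-fold higher (1.65 to 1.80) in monocyte/macrophage-like cells, which held 28.0% of its UMIs in sham and 79.5% in tenotomy. Ccl2, a monocyte chemokine (chromosome 11, 82035571 to 82037453), was 4.36-fold higher (4.23 to 4.49) in mesenchymal progenitor-like cells and 2.53-fold lower in both monocyte/macrophage-like (2.45 to 2.61) and muscle stem cell-like cells (2.31 to 2.76). In muscle stem cell-like cells, which had more UMIs per cell in tenotomy, Ccl2 had 954 UMIs in 500 sham and 995 in 525 tenotomy cells. There, 23.8% of sham and 36.8% of tenotomy cells carried a Ccl2 UMI. Mesenchymal progenitor-like cells held 32.4% of Ccl2 UMIs in sham and 61.9% in tenotomy, and 68.3% and 75.7% of those of Csf1, a macrophage growth factor. Csf1 was 1.33-fold higher (1.27 to 1.40) and Igf1 1.33-fold lower (1.30 to 1.36) in that class. An Igf1 UMI was seen in 86.3% of its sham and 89.3% of its tenotomy cells. Igf1 was also 2.17-fold lower (1.77 to 2.67) in muscle stem cell-like cells. After thinning of the cells, its log2 fold in muscle stem cell-like cells was 0.0313, so its direction there depends on depth. Yap1 and Wwtr1 encode the coactivators YAP and TAZ. As shares of UMIs, they were 1.78-fold (1.63 to 1.95) and 1.25-fold (1.197 to 1.303) lower in mesenchymal progenitor-like cells. A Yap1 UMI was seen in 36.3% of sham and 38.8% of tenotomy cells of that class, and a Wwtr1 UMI in 76.5% and 82.4%. In muscle stem cell-like cells Yap1 and Wwtr1 were 2.19-fold (1.81 to 2.66) and 1.84-fold (1.68 to 2.01) lower. There, a Yap1 UMI was seen in 29.0% of sham and 32.8% of tenotomy cells, and a Wwtr1 UMI in 71.0% and 76.6%. In blood endothelial cell-like cells Yap1 was 1.35-fold higher (1.18 to 1.55) and Wwtr1 within counting error at 1.01-fold (0.960 to 1.06).

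Cells with cycle transcripts were more frequent in the tenotomy library in muscle stem cell-like, mesenchymal progenitor-like and blood endothelial cell-like cells. Among muscle stem cell-like cells thinned to 1000 UMIs, 1 of 499 sham cells (0.200%, 0.00507 to 1.11) and 125 of 517 tenotomy cells (24.2%, 20.6 to 28.1) carried at least 2 UMIs of the 12 cycle genes, with 1 sham and 8 tenotomy cells left out as shallow. Without thinning the shares were 0.800% and 51.6%. Among mesenchymal progenitor-like cells, 1 of 1853 (0.0540%) and 183 of 1756 (10.4%, 9.03 to 12.0) did so, with 14 and 29 cells left out, and 0.964% and 38.1% without thinning. In blood endothelial cell-like cells the shares were 0.0947% and 2.26%, with 103 and 136 cells left out, and 0.520% and 5.17% without thinning. In monocyte/macrophage-like cells they were 1.85% (0.748 to 3.78) and 3.53% (3.00 to 4.11), with 23 and 140 cells left out and overlapping intervals, and 4.99% and 12.7% without thinning. Neutrophil-like cells gave 8.57% (3.21 to 17.7) and 10.7% (8.35 to 13.5). Tenocyte-like cells gave 0 of 391 cells, which taken at 3 counts allows a share of up to 0.767% (exact interval up to 0.939%), and 0.995% (0.121 to 3.55). Pericyte or smooth muscle-like cells gave 0.340% (0.00861 to 1.88) and 1.60% (0.330 to 4.59), and the intervals of these 3 classes overlapped. Mki67, a marker of dividing cells, was 36.1-fold higher (23.6 to 58.5) in muscle stem cell-like, 39.8-fold higher (28.0 to 58.8) in mesenchymal progenitor-like, 70.2-fold higher (35.1 to 164) in blood endothelial cell-like and 1.76-fold higher (1.45 to 2.16) in monocyte/macrophage-like cells. In 3 other settings the difference in muscle stem cell-like cells was 0 to 3.99 percentage points, with separate clustering it was 29.5 points, and that in mesenchymal progenitor-like cells was 0.978 points at resolution 2 and 6.35 points with separate clustering, as given with the other settings in the closing section.

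**Figure D4:**
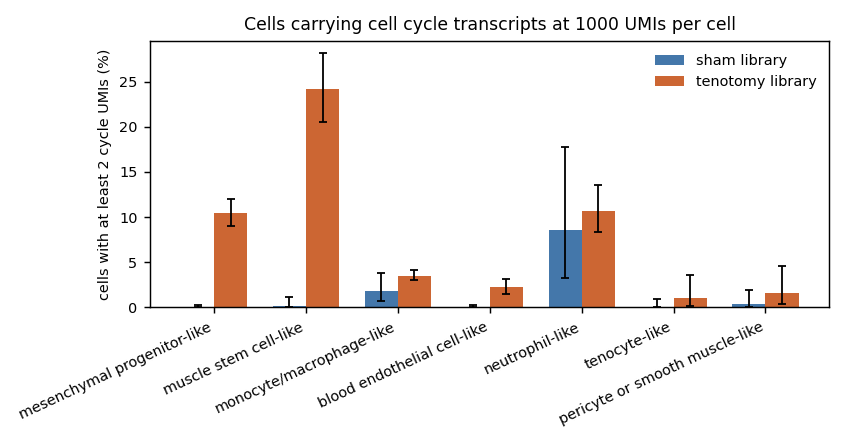
Share of cells in percent with at least 2 UMIs of 12 cycle genes after thinning to 1000 UMIs per cell, by class and library, with exact 95% intervals for counting error as bars. Muscle stem cell-like cells reached 24.2% and mesenchymal progenitor-like cells 10.4% in the tenotomy library, against 0.200% and 0.0540% in the sham library.

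Tenocyte-like and pericyte or smooth muscle-like cells were compared in the same way. Of 3106 genes measured in 397 sham and 206 tenotomy tenocyte-like cells, 184 were at least 2-fold higher and 196 lower. Mmp13, a collagenase gene (chromosome 9, 7272514 to 7283331), had 1 UMI in sham and 436 in tenotomy, a ratio of 1027 (183 to 40648), and Mmp3, the gene of stromelysin 1, was 78.4-fold higher (37.4 to 197). The acute phase genes Saa1, Serpina3n and Lcn2 were 67.5-fold (3 UMIs in sham, 22.3 to 334), 22.4-fold (17.5 to 29.1) and 18.0-fold (15.2 to 21.5) higher, and Chil1 15.8-fold higher. Iigp1, Ccl21a, Itih5, Mt3, C1qtnf4 and S100a5 were 8.62-fold to 32.5-fold lower. Of 23 chemokine and cytokine genes, 17 were at least 2-fold higher and 1 lower in tenocyte-like cells, with a median log2 fold of 1.78. Inflammatory monocyte and resident macrophage genes had medians of 1.71 and 0.74 there, and C1qa stood at 2.32% of its macrophage level in sham and 5.54% in tenotomy. In the same class, matrix genes had a median of 0.11 with 11 of 43 at least 2-fold higher and 6 lower. In 296 sham and 191 tenotomy pericyte or smooth muscle-like cells, 180 of 3594 genes were at least 2-fold higher and 208 lower. Timp1 was 65.0-fold higher (24.8 to 242), Slc7a11, with 1 UMI in sham, had a ratio of 160 (28.0 to 6389), and Pclaf, with 0 UMIs in sham, was at least 38.2-fold higher. The neutrophil genes Retnlg, S100a9 and S100a8 were among the 6 highest, with S100a9 at 26.4% of its level over all tenotomy cells. Car2, Timp4, Depp1, Igfbp3, Txnip and Cdkn1c were 4.08-fold to 12.1-fold lower. Timp4, Depp1 and Igfbp3 were also among the leading genes of blood endothelial cell-like clusters, and the source of their transcripts in this class was not tested.

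The 3 classes with fewest sham cells gave coarser values. Among 70 sham and 685 tenotomy neutrophil-like cells, 61 of 2884 genes were at least 2-fold higher and 97 lower, led by Ccl21a at least 19.3-fold, Tnf at 15.1-fold (8.15 to 31.7) and Pf4 at 18.7-fold (7.92 to 57.9). C1qc, S100a4 and Ccl3 were also higher, and the lower genes Ccl11, Igfbp5, Myoc, Meg3, Serping1 and Lum are mostly genes of mesenchymal cells. Resident macrophage genes had a median log2 fold of 2.53 in this class, and C1qa stood at 0.038% of its macrophage level in sham and 3.5% in tenotomy. Among 53 sham and 236 tenotomy B cell-like cells, 356 of 2716 genes were at least 2-fold higher and 121 lower. The higher genes Cxcl2, Il1b, Lgals3, Fcer1g and Spp1 are myeloid genes, and C1qa stood at 17.3% of its macrophage level in B cell-like cells of the tenotomy library. The lower genes Timp4, Dcn, Ogn, Gsn, Plagl1 and Tcim include endothelial and mesenchymal genes. Myofibre-like cells are described with the other observations.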

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

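The marrow marker genes used in this part were chosen after the clusters had been seen, and no explanation for the items below was tested before that.

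Cluster 27 held 0.330% of tenotomy cells (36 cells) and 0.0662% of sham cells (5 cells). It stands here because it was left without a class name and so was not analysed. Its leading genes Ccr9, Siglech, Bcl11a and Spib are known from plasmacytoid dendritic cells, a type that had no list of its own here. Siglech was also 68.9-fold lower in monocyte/macrophage-like cells of the tenotomy library.

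Cluster 30 held 0.156% of tenotomy cells (17 cells) and 0 of 7548 sham cells. Its leading genes joined haemoglobin and erythroid genes such as Alas2 with the macrophage genes Ccl12 and Ccl8. Cluster 38 held 0.321% of tenotomy cells (35 cells) and 1 sham cell, with Vpreb3, Pou2af1, histone genes and Top2a in the lead, which are genes of dividing cells of the B lineage. Both had no class name and stayed outside the comparisons. Over all cells, erythroid precursor genes marked 0.0685% of sham and 1.12% of tenotomy cells, and B cell precursor genes 0.233% and 0.987%.

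Ccl2 differed in opposite directions between the classes, with a log2 fold of 2.12 in mesenchymal progenitor-like cells and −1.34 in monocyte/macrophage-like cells. It stands here because the classes gave different answers for 1 gene. The difference between the classes was not tested.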

How the results depend on the processing

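The settings with automatic doublet calls, a second class of up to 0.6 and no cycling cells were chosen after the data had been seen, and all others before. Ratios of shares are tenotomy over sham, and differences in cells with cycle transcripts are tenotomy minus sham in percentage points.

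At the settings of the report, the ratios of shares were 0.319 for blood endothelial cell-like, 0.661 for mesenchymal progenitor-like, 7.91 for monocyte/macrophage-like and 0.726 for muscle stem cell-like cells. The differences in cells with cycle transcripts were 2.16, 10.4, 1.68 and 24.0 points in that order. Over the settings of filter, doublets, clustering and naming, and without erythroid cells and neutrophils, the ratios of shares ranged in that order from 0.303 to 0.341, from 0.389 to 0.706, from 5.32 to 10.4 and from 0.301 to 0.775. Among cells other than monocyte/macrophage-like cells, the ratios of mesenchymal progenitor-like and muscle stem cell-like cells were 1.08 and 1.19, so their direction depends on the base.

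At resolution 2 the ratio was 0.390 for mesenchymal progenitor-like, 8.86 for monocyte/macrophage-like and 0.455 for muscle stem cell-like cells, the cycling differences of the first and last were 0.978 and 1.82 points, and 327 genes were higher and 390 lower in mesenchymal progenitor-like cells. With the libraries clustered separately the 3 ratios were 0.389, 9.10 and 0.589, the cycling differences were 6.35 and 29.5 points, 331 genes were higher in monocyte/macrophage-like cells, and the Pi16/Dpp4 list in mesenchymal progenitor-like cells changed sign to 0.29. Without the 3304 genes 2-fold apart, the ratio was 10.4 for monocyte/macrophage-like and 0.493 for muscle stem cell-like cells, whose cycling difference was 3.99 points and whose low lists numbered 4. At resolution 0.5 the ratio of monocyte/macrophage-like cells was 5.32, their high lists numbered 5, and their chemokine list changed sign to −0.0836. With a second class of up to 0.6 the ratio of mesenchymal progenitor-like cells was 0.581.

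Part of this lay in clusters left unnamed. At resolution 2, unnamed clusters nearest to mesenchymal progenitors held 388 sham and 813 tenotomy cells and those nearest to muscle stem cells 1 and 194, and with them the ratios were 0.574 and 0.720. With separate clustering, the first held 375 and 798 cells, and the ratio with them was 0.569. The cause of the other differences was not tested.

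Settings of the cell filter moved several values. With at most 20% mitochondrial UMIs the ratio was 0.577 for mesenchymal progenitor-like and 0.301 for muscle stem cell-like cells, and in the latter the cycling difference was 0 points, 626 genes were higher and 353 lower, while 120 tenotomy cells nearest to that class stayed unnamed. With at most 5% the ratio of monocyte/macrophage-like cells was 9.47, their high lists numbered 5, their chemokine list changed sign to −0.00335, and the cycling difference of muscle stem cell-like cells was 29.6 points. With predicted doublets kept, low lists numbered 4 in mesenchymal progenitor-like and 4 in muscle stem cell-like cells, and the capillary list in the latter changed sign to 0.35. With automatic doublet calls, low lists numbered 4 in mesenchymal progenitor-like cells. Among cells other than erythroid cells and neutrophils, the ratios were 0.341 for blood endothelial cell-like and 0.706 for mesenchymal progenitor-like cells.

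Without thinning, the cycling differences were 4.65 points in blood endothelial cell-like, 37.1 in mesenchymal progenitor-like, 7.76 in monocyte/macrophage-like and 50.8 in muscle stem cell-like cells, and with 1 UMI as the limit they were 4.07, 19.9, 5.92 and 34.2 points. With cells thinned to 1000 UMIs, 359 genes were higher in monocyte/macrophage-like cells and low lists numbered 3 in muscle stem cell-like cells. The log2 fold of Igf1 in muscle stem cell-like cells changed sign from −1.12 to 0.0313, and the Pi16/Dpp4 list in mesenchymal progenitor-like cells to 0.26. As a mean over cells, 144 genes were lower in blood endothelial cell-like cells, and the Pi16/Dpp4 list changed sign to 0.0515. After subtraction of 5% free RNA the capillary list changed sign to 0.98 in mesenchymal progenitor-like and 3.26 in muscle stem cell-like cells, so its direction there is not held as a result. Without the cells carrying at least 2 cycle UMIs before thinning, 369 genes were higher in mesenchymal progenitor-like cells.

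The expression limit set the gene counts. At 20 CPM, 362 genes were higher in blood endothelial cell-like, 929 in mesenchymal progenitor-like, 314 in monocyte/macrophage-like and 1934 in muscle stem cell-like cells, and 369, 1006 and 503 were lower in the first 3. At 200 CPM, 68, 217, 80 and 241 genes were higher and 91, 226, 77 and 242 lower.

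A value counts here as near the reported one if it lay within its 95% counting interval, and a count if it lay within 1.5 times the reported count. For genes given by name, 383 comparisons stayed near, 303 moved and 1 was counted as reversed, and for lists 945, 475 and 8. Only sign changes of genes at least 2-fold apart, or of lists outside the central 95% of random lists, were counted as reversed. Other sign changes stand among the values that stayed near or moved, so these counts do not give all changes of direction. Gene counts stayed near in 129 comparisons and moved in 23, counts of lists in 113 and 7, shares in 29 and 15, and cells with cycle transcripts in 33 and 15.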

Other observations

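Myofibre-like cells of the tenotomy library carried more transcripts of Csrp3, Ankrd2 and Ankrd1, genes with known roles in the response of muscle to stretch. Of 946 genes measured in 54 sham and 72 tenotomy cells, 117 were at least 2-fold higher and 123 lower. The class had medians of 2486.5 UMIs and 0.0379% mitochondrial UMIs per cell in sham, and of 1373 and 0.165% in tenotomy. Over all kept cells the mitochondrial medians were 3.18% and 3.11%, so the barcodes of this class may not be intact cells. Csrp3, the gene of muscle LIM protein (chromosome 7, 48830398 to 48848033), had 5 UMIs in sham and 1345 in tenotomy, 419-fold higher (179 to 1293). Ankrd2 and Ankrd1, which encode ankyrin repeat proteins of the sarcomere, had 0 UMIs in sham and were at least 90.9-fold and at least 44.7-fold higher. Myh2, a myosin of fast oxidative fibres, was at least 31.2-fold higher, and Hspb7, a small heat shock protein, 34.7-fold higher (19.5 to 67.9). Fbxl22 had 1 UMI in sham and a ratio of 112 (19.5 to 4491).

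Matrix genes in myofibre-like cells had a median log2 fold of −1.68, with 8 of 13 at least 2-fold lower and 1 higher. In mesenchymal progenitor-like cells the median over 43 measured members was 1.05, with 10 at least 2-fold lower, and the difference between the classes was not tested. Gsn and Dcn were 81.7-fold and 34.3-fold lower, and in the sham class they stood at 17.9% and 14.9% of their level over all sham cells. Both were also lower in mesenchymal progenitor-like cells. Amd1, an enzyme of polyamine synthesis, was 9.92-fold lower (5.67 to 19.0).

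Of the tests that follow, those on endothelial cells, marrow cells and handling were written after the results had been seen, and the one on dividing cells used a setting added after the data had been seen.

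The higher share of monocyte/macrophage-like cells was weighed against other explanations. Fewer endothelial cells alone would give all other classes the same ratio, but without them the ratio was 5.21 for this class and 0.435 and 0.478 for mesenchymal progenitor-like and muscle stem cell-like cells. More blood would not raise cells rich in C1q, a complement gene group of tissue macrophages, and the ratio of such cells was 6.66 (5.97 to 7.43). Cells with marrow precursor genes outside the class numbered 0.135 per macrophage in tenotomy and 0.233 in sham. How many marrow would bring was not measured, so marrow as a source stays open.

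The higher matrix and TGF-beta response genes in mesenchymal progenitor-like cells were weighed in the same way over the 28 list members at least 2-fold higher, which had a median log2 fold of 2.02. Pericytes mixed into the class would have to make up 25.8% of the pericyte level to supply Acta2, and 9 other pericyte markers stood at a median of 0.402%, the highest being Cspg4 at 13.6%. After thinning to 1000 UMIs their median was 1.87, and those of the whole matrix and TGF-beta lists were 0.73 and 1.04, still above at least 99.99% of random lists, so depth is not the whole cause. Without the cells carrying at least 2 cycle UMIs before thinning, which left 1849 sham and 1105 tenotomy cells, the 3 medians were 1.99, 0.99 and 1.31, so dividing cells alone do not explain it.

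Immediate early and stress genes were lower in the tenotomy library in 9 of 9 classes, with medians from −2.32 to −0.21. After subtraction of 5% free RNA, the median nearest to 0 in the 4 main classes was −1.11, against −1.15 before. The share of 5% was a setting and was not measured, and its subtraction moved this median little. This test therefore cannot decide on free RNA, which stays open. Over 15 clusters built without genes 2-fold apart the middle value was −0.96, with 14 of them below 0, but such clusters pool states that the full clustering separates, so other cell states stay open. Handling of the libraries, free RNA, other cell states and an effect of tenotomy cannot be told apart, because treatment and library coincide.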
